A study of Mus musculus with 12 samples.

How the data were processed

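Liver RNA of 12 mice was hybridised to dual-colour oligonucleotide arrays (Compugen mouse 22K set), 1 mouse per array. The mice were wild type or gp130F/F, on a mixed C57BL/6 and 129SV background, and all are labelled female and 12 weeks old. Each of the 4 groups, wild type and gp130F/F with and without LPS, has 3 mice by the labels. The deposited names of gp130F/F controls 2 and 3 share a number. They are taken as separate mice, as labelled, and their Xist ratios differ (-0.01 and -1.77), but a repeat of 1 mouse would leave 2 mice in that group. Per the labels, total RNA was taken with Trizol and RNeasy columns, then amplified and labelled with the amino allyl MessageAmp II kit. Liver carries the green dye (Alexa Fluor 555), and the reference, pooled RNA of C57BL/6 embryos at 17.5 days post coitus, the red dye (Alexa Fluor 647). The dyes were not swapped on any array. The labels describe no injection of the control mice, so effects of the injection itself are not separated from those of LPS.

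The deposited scanner files hold, per the file headers, the intensity of each spot and of its local background in both channels, with no background subtracted. The scanner and the image software are not given in the sources used here. A table by the authors holds the linear ratio of each probe after lowess normalization, and its values show that the authors divided each probe by the median of the 3 controls of the same genotype. The authors' second table holds the log2 of those ratios. In it the median over 21545 probes was 0 on the 6 control arrays, -0.05 on each wild type LPS array, and 0.01, 0.02 and 0.02 on the gp130F/F LPS arrays. Because of that division the authors' values carry no difference between the genotypes at one treatment, so the scanner intensities were used here.

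Each array has 23040 spots, of which 1013 are controls, and the image software marked 0 spots as bad. Foreground was the spot mean and background the spot median of the surroundings. Background was corrected with normexp (offset 50), and ratios were normalized with loess over the whole array, control spots given no weight. Values were not scaled between arrays. Spots of 5 probes printed at 2 places were averaged, which left 22022 probes. Such spots did not always agree. For Orm2 the liver intensity ran from 480 to 1197 on 1 spot and from 2365 to 48640 on the other, so its averaged ratio mixes unlike spots. Per array the median liver intensity was 840 to 1348 over a background of 47 to 64, and the median reference intensity 1798 to 2628 over 83 to 108. Empty and buffer spots had a median liver intensity of 83.5 to 161. A spot was counted as near the scanner ceiling when its median reached 60000, or its mean reached 25000 and exceeded 0.95 times its median. That held for 95 to 176 liver spots and 274 to 409 reference spots per array. The number of arrays limits the precision.

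Gene names come from the scanner files' accession (6738 probe spots), the symbol in the probe's description (1079), a RIKEN clone (5690) or that description alone (342), matched to the RefSeq annotation of the mouse genome (GRCm38). No name was found for 8178 probe spots. The 12799 names include 679 with more than 1 probe, each represented by its brightest probe.

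A linear model with 1 coefficient per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (prior degrees of freedom 2.97). The comparisons were LPS against control in each genotype, gp130F/F against wild type at each treatment, and the interaction. Limma's p-values were adjusted by the Benjamini-Hochberg method over all probes of a comparison, with a threshold of 0.05, and "called" or "passed" means under it. Errors after ± are standard errors from this model. The size of the LPS response was compared by an exact permutation test of genotype within treatment, over probes called for the LPS effect averaged over genotypes. The groups, tests, gene lists and most alternatives were fixed before the data were examined. So was the rule for naming genes: the 8 probes with a single gene name that rose most and the 8 that fell most among called probes without overlap between groups (without that condition for the interaction), up to 4 called members of each list, and Il6st, Socs3, Stat3, Tlr4, Cd14, Lbp, Ly96, Saa1, Saa2, Il6 and Tnf whatever their value. The text does not name every gene that the rule selects.

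The 26 gene lists cover immune signalling, liver metabolism, stress and markers of other cell types. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and also with an estimated correlation and with fry. Camera asks whether a list's members changed more than other genes. Counts of called members are also given adjusted over the list alone.

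The alternatives were no background correction, plain subtraction, median centring, scaling and Aquantile between arrays, the authors' values, filters on dim or poorly detected spots, a replicate block, fits of the compared groups alone, array weights, a trended and robust prior, and each array left out. Further alternatives, chosen after the data had been seen, were the liver channel alone, spot medians, leaving out spots near the ceiling, leaving out the 3 arrays with high Xist, and Xist class as a covariate.

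In the authors' tables, 3 stretches of probe names (29, 144 and 56 probes) are shifted by 1 spot against the scanner files. Elsewhere 97.4% of probes lay nearest to the authors' row of the same name, and in the stretches 92.1% lay nearest to the row before. These 229 probes were left out when the authors' values were used. Outside them, over 4846 probes called with LPS, the median correlation with the authors' values across arrays was 0.992.

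The fit and the permutation test were run on simulated log ratios with each probe's spread on these arrays. Background correction, loess and the scanner ceiling were not simulated. The simulated arrays were independent and equally variable, which the real arrays were not, so the rates below do not cover the whole procedure. Of 100 probes per comparison with a log2 change of 1, 74% to 79% were called in the comparisons of a pair of groups and 49% in the interaction. With a log2 change of 2 these values were 99% and 97%. Between 5.98% and 8.75% of calls were false, above the nominal level. Without any change limma called 0 probes in each pair comparison and 1 in the interaction. A single simulated response smaller by 0.3 gave an exact permutation p = 0.065, and how often such a difference would pass was not measured.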

Results

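Gene expression was measured in the livers of 12 mice of 2 genotypes, aged 12 weeks. The gp130F/F mice carry a knock-in allele of gp130 (gene Il6st), the signalling chain shared by the receptors of interleukin-6 and related cytokines. In this allele a phenylalanine replaces the tyrosine that binds the inhibitor SOCS3. In each genotype 3 mice received lipopolysaccharide (LPS, 4 mg/kg, into the peritoneum) and their livers were taken after 6 hours. The other 3 mice were controls, for which the labels name no injection. Each liver was hybridised to an array against pooled RNA of whole mouse embryos, so every value is a log2 ratio of liver over embryo reference. The study concerns the hypersensitivity of these mutants to LPS. The comparisons ask how each genotype responded, how the genotypes differed at each treatment, and whether the responses differed.

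On each array 22022 probes were tested, which name 12799 genes. The median liver spot intensity lay between 840 and 1348 per array, over a local background of 47 to 64. Between 95 and 176 liver spots per array lay near the scanner ceiling. Across probes, which are not independent replicates, arrays of a group correlated with r from 0.896 to 0.966 in wild type controls and 0.941 to 0.957 in wild type mice with LPS. In gp130F/F the range was 0.806 to 0.942 in controls and 0.929 to 0.974 with LPS. The number of arrays, 3 per group, limits the precision. Xist, the transcript that silences an X chromosome in females, had log2 ratios between -0.01 and 0.56 on 3 control arrays, wild type control 3 and gp130F/F controls 1 and 2. On the other 9 arrays it lay between -3.44 and -1.77, although all mice are labelled female. The mutated gene, Il6st, is expressed from the knock-in allele, so its level does not check the genotype labels.

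The first comparison asks how wild type livers responded to LPS. Inflammatory and interferon-induced genes rose most. Cxcl1, a chemokine for neutrophils, rose by a log2 change of 4.98 ± 0.20 (SE, n = 3 mice per group here and throughout), with its LPS spots near the scanner ceiling. Its name is that in the scanner files, from which the authors' tables differ by 1 spot at this place. Other large rises were in Fhod3 (4.57 ± 0.55), the interferon-induced Cmpk2 (4.23 ± 0.27), Tgtp1 (4.2 ± 0.26), Gbp2 (4.14 ± 0.20), the secreted lectin Reg3b (4.13 ± 0.36) and the transporter Slc10a6 (4.00 ± 0.41). The largest falls were in the iron exporter Slc40a1 (-3.22 ± 0.28), the triglyceride synthesis enzyme Gpam (-2.98 ± 0.31), the succinate receptor Sucnr1 (-2.74 ± 0.28) and the water channel Aqp8 (-2.57 ± 0.41). The lipase inhibitor G0s2 (-2.56 ± 0.22), Fam89a (-2.56 ± 0.40), Cyp4a14 (-2.48 ± 0.73) and Vwce (-2.35 ± 0.22) followed. Limma's adjusted p for these genes ranged from 1.88e-07 (Cxcl1) to 0.0418 (Cyp4a14). In all, 3448 of 22022 probes passed, 1922 higher and 1526 lower, of which 626 rose and 287 fell by at least 2-fold. The balance was 1375 higher and 1471 lower with median centring, 1605 and 1599 in the authors' values and 694 and 242 in the liver channel alone.

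Interferon-induced genes were 34 higher and 0 lower of 37 (35 and 0 adjusted over the list alone), with a median log2 change of 1.46. Among them were the GTPases Ifi47 (3.89 ± 0.19) and Irgm1 (3.84 ± 0.17). Interferon genes gave camera adjusted p = 3.48e-30, and adjusted p = 0.0195 with an estimated correlation. Cytokines and chemokines were 18 higher and 1 lower of 37 (21 and 1 adjusted over the list alone), including Cxcl10 (2.91 ± 0.17) and Ccl5 (2.68 ± 0.21). Cytokines and chemokines gave camera adjusted p = 3.33e-09, and adjusted p = 0.0905 with an estimated correlation. The list of gp130 and STAT3 signalling had 15 higher and 2 lower of 32 (18 and 2 adjusted over the list alone). The cytokine signal inhibitors Socs1 (3.71 ± 0.11) and Socs3 (2.76 ± 0.30) rose, as did Stat3 (1.08 ± 0.12) and Il6st (0.58 ± 0.16). gp130 and STAT3 signalling gave camera adjusted p = 3.63e-07, and adjusted p = 0.0728 with an estimated correlation. The list of TLR4 and NF-kB signalling had 12 higher and 2 lower of 29 (12 and 4 adjusted over the list alone). The LPS co-receptor Cd14 rose by 3.49 ± 0.34, the LPS-binding protein Lbp by 2.35 ± 0.16, the adaptor Myd88 by 1.69 ± 0.16 and the TLR4 partner Ly96 by 0.52 ± 0.14. The size for Cd14 is not exact, as its spots were near the ceiling on 2 of the 3 LPS arrays. TLR4 and NF-kB signalling gave camera adjusted p = 0.00107, and adjusted p = 0.176 with an estimated correlation. Tlr4 (-0.29 ± 0.10, adjusted p = 0.0618) and Tnf (0.29 ± 0.17, adjusted p = 0.281) did not pass limma's test, and no probe is named for Il6.

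Cell death genes were 20 higher and 0 lower of 31 (22 and 1 adjusted over the list alone), including the growth arrest genes Gadd45a (1.88 ± 0.18) and Cdkn1a (2.50 ± 0.32). Cell death genes gave camera adjusted p = 6.14e-11, and adjusted p = 0.0706 with an estimated correlation. Acute phase proteins were 8 higher and 3 lower of 20 (9 and 3 adjusted over the list alone), with Serpina3c (2.85 ± 0.23) and Crp (1.66 ± 0.17) higher. The size for Crp is not exact, as it was near the ceiling on 1 of the 3 LPS arrays. Acute phase proteins gave camera adjusted p = 0.0147, and adjusted p = 0.233 with an estimated correlation. The ratios of the serum amyloid genes Saa1 (-1.39 ± 0.20) and Saa2 (-0.74 ± 0.17) were lower, but their spots were uneven and near the ceiling. The liver channel alone gave 1.49 for Saa1 and 2.41 for Saa2, and spot medians gave -0.07 and 0.41. Coagulation and fibrinolysis genes were 8 higher and 0 lower of 22 (8 and 1 adjusted over the list alone). Coagulation genes gave camera adjusted p = 0.00553, and adjusted p = 0.0706 with an estimated correlation. Complement genes were 3 higher and 0 lower of 19 (5 and 0 adjusted over the list alone). Complement genes gave camera adjusted p = 0.009, and adjusted p = 0.167 with an estimated correlation. Neutrophil markers were 4 higher and 0 lower of 19 (8 and 0 adjusted over the list alone), including S100a8 (2.63 ± 0.35) and S100a9 (2.79 ± 0.41). Neutrophil markers gave camera adjusted p = 0.00147, and adjusted p = 0.281 with an estimated correlation. Secretory proteins of the liver that fall in other acute phase responses were 4 higher and 1 lower of 18 (7 and 1 adjusted over the list alone). These secretory proteins gave camera adjusted p = 0.035, and adjusted p = 0.281 with an estimated correlation. These secretory proteins ranged from 0.0134 to 0.113 by camera with 1 array left out, and lost the call without wild type control 2 (0.113) and wild type LPS 2 (0.0606). Their test turned downward, with a median of 0.05, when arrays were scaled to equal spread.

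Fatty acid oxidation and ketogenesis genes were 1 higher and 8 lower of 24 (1 and 10 adjusted over the list alone). This fatty acid list gave camera adjusted p = 0.0254, and adjusted p = 0.744 with an estimated correlation. The fatty acid list ranged from 0.00642 to 0.0667 by camera with 1 array left out, and lost the call without wild type control 1 (0.0667) and wild type LPS 3 (0.0612). The other metabolic and stress lists did not pass. Xenobiotic metabolism was 6 higher and 2 lower of 47 (8 and 2 adjusted over the list alone) with camera adjusted p = 0.125, and its median of 0.23 became -0.26 when arrays were scaled to equal spread. Glucose and amino acid metabolism was 5 higher and 4 lower of 26 (9 and 4 adjusted over the list alone) with camera adjusted p = 0.509, and its median of 0.10 became -0.40. Its member Pck1, the entry enzyme of glucose synthesis, had a ratio higher by 1.00 ± 0.28 against -0.02 in the liver channel alone, and G6pc fell (-1.42 ± 0.34, against -4.05 in the liver channel alone). Bile acid synthesis and transport was 3 higher and 3 lower of 26 (4 and 4 adjusted over the list alone) with camera adjusted p = 0.907, and the bile acid receptor Nr1h4 (-1.25 ± 0.23) and the exporter Abcc2 (-1.08 ± 0.17) fell. Its median was -0.07, its mean 0.07 and its test downward. Lipogenesis and cholesterol synthesis was 3 higher and 2 lower of 24 (5 and 3 adjusted over the list alone) with camera adjusted p = 0.948. Endoplasmic reticulum and heat shock stress was 7 higher and 2 lower of 24 (8 and 4 adjusted over the list alone) with camera adjusted p = 0.0846. Oxidative and metal stress was 5 higher and 3 lower of 22 (5 and 3 adjusted over the list alone) with camera adjusted p = 0.549, and the heme-degrading Hmox1 rose (2.35 ± 0.34). Circadian clock genes were 2 higher and 3 lower of 15 (2 and 4 adjusted over the list alone) with camera adjusted p = 0.782, the clock output Dbp falling (-2.06 ± 0.43) and Nfil3 rising (1.90 ± 0.19).

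No list of other cell types passed in wild type livers apart from neutrophils. Macrophage and Kupffer cell markers were 3 higher and 3 lower of 16 (3 and 3 adjusted over the list alone) with camera adjusted p = 0.547. The scavenger receptor Marco rose (2.62 ± 0.54), and Cd5l (-1.62 ± 0.36) and Mrc1 (-1.65 ± 0.19) fell. Lymphocyte markers were 4 higher and 0 lower of 24 (4 and 0 adjusted over the list alone) with camera adjusted p = 0.0587. Endothelial markers were 4 higher and 2 lower of 15 (6 and 2 adjusted over the list alone) with camera adjusted p = 0.547, and the adhesion molecule Icam1 rose (3.03 ± 0.37). Stellate cell and fibroblast markers were 3 higher and 0 lower of 17 (3 and 0 adjusted over the list alone) with camera adjusted p = 0.598. Cholangiocyte markers were 0 higher and 2 lower of 12 (0 and 3 adjusted over the list alone) with camera adjusted p = 0.598. Erythroid markers were 0 higher and 0 lower of 11 (0 and 0 adjusted over the list alone) with camera adjusted p = 0.593, and cell cycle genes 0 higher and 0 lower of 26 (0 and 0 adjusted over the list alone) with camera adjusted p = 0.333. Transcripts of pancreas and muscle, a check for other tissue, were 0 higher and 0 lower of 17 (0 and 0 adjusted over the list alone) with camera adjusted p = 0.882. The test pointed away from the median for stellate cell (-0.06, upward) and cholangiocyte markers (0.04, downward) and for endothelial markers, whose median was just under 0. It pointed away from the mean for cholangiocyte (0.01) and for pancreas and muscle transcripts (0.04).

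With 1 array left out, the wild type count of 3448 moved by over 1.5 times without control 2 (2266 probes) and without LPS 2 (2154). Of 46 called genes named, 40 passed in all 12 such fits, and Cyp4a14, Il6st, Ly96, Pck1, G6pc and Saa2 did not. With Xist class as a covariate Cyp4a14, Pck1 and Ly96 lost the call, and without the 3 arrays with high Xist Pck1 and Ly96 did. In the liver channel alone secretory proteins and complement lost the camera call, and bile acid genes gained one, downward. Among wild type arrays, calls ended without control 1 (4 genes, adjusted p up to 0.123), control 2 (3, 0.108), control 3 (4, 0.118), LPS 1 (4, 0.0995), LPS 2 (5, 0.126) and LPS 3 (4, 0.137). Among gp130F/F arrays, they ended without control 2 (1 gene, adjusted p up to 0.0579), LPS 1 (1, 0.0579), LPS 2 (2, 0.0615) and LPS 3 (1, 0.0534).

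The second comparison asks how gp130F/F livers responded to LPS. The largest rises were in Slc10a6 (4.79 ± 0.41), the interferon-induced Ifit2 (4.18 ± 0.27), Cmpk2 (4.08 ± 0.27) and Got1l1 (3.28 ± 0.81). Socs1 (3.18 ± 0.11), the phosphodiesterase Pde4b (2.96 ± 0.20), Slc38a9 (2.96 ± 0.55) and Gadd45a (2.95 ± 0.18) followed. The largest falls were in Slc40a1 (-3.28 ± 0.28), Anks4b (-3.02 ± 0.32) and Gpam (-2.90 ± 0.31) and in Alas1, the first enzyme of heme synthesis (-2.65 ± 0.37). Sult3a1 (-2.63 ± 0.73), Zfyve21 (-2.61 ± 0.18), Raet1c (-2.20 ± 0.31) and the cholesterol transporter Npc1 (-2.15 ± 0.32) followed. The adjusted p of these 16 genes ranged from 3.4e-07 (Socs1) to 0.0378 (Sult3a1). In all, 2867 probes passed, 1027 higher and 1840 lower, of which 477 rose and 371 fell by at least 2-fold. The balance turned over in the liver channel alone, with 380 higher and 223 lower.

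Interferon-induced genes were 22 higher and 0 lower of 37 (24 and 0 adjusted over the list alone), with a median log2 change of 1.09, and included Gbp2 (2.75 ± 0.20) and Ifi47 (2.58 ± 0.19). Interferon genes gave camera adjusted p = 1.66e-18, and adjusted p = 0.0874 with an estimated correlation. Cytokines and chemokines were 11 higher and 2 lower of 37 (14 and 3 adjusted over the list alone), with Cxcl10 (2.51 ± 0.17) and Cxcl11 (2.21 ± 0.23) higher. Cytokines and chemokines gave camera adjusted p = 1.7e-04, and adjusted p = 0.346 with an estimated correlation. Cell death genes were 13 higher and 0 lower of 31 (14 and 1 adjusted over the list alone). Cell death genes gave camera adjusted p = 3.75e-05, and adjusted p = 0.295 with an estimated correlation. The list of gp130 and STAT3 signalling had 10 higher and 3 lower of 32 (14 and 3 adjusted over the list alone). Socs3 (1.42 ± 0.30) and Stat3 (0.54 ± 0.12) rose, and Il6st (-0.20 ± 0.16, adjusted p = 0.457) did not pass, its 2 probes differing in sign. gp130 and STAT3 signalling gave camera adjusted p = 2.23e-04, and adjusted p = 0.295 with an estimated correlation. The list of TLR4 and NF-kB signalling had 8 higher and 3 lower of 29 (10 and 4 adjusted over the list alone). TLR4 and NF-kB signalling gave camera adjusted p = 0.0295, and adjusted p = 0.468 with an estimated correlation. TLR4 and NF-kB signalling ranged from 0.00498 to 0.294 by camera with 1 array left out, and lost the call without gp130F/F control 3 (0.294). Cd14 rose by 1.33 ± 0.34, with its LPS spots near the ceiling. Lbp (0.29 ± 0.16, adjusted p = 0.256), Ly96 (-0.01 ± 0.14, adjusted p = 0.972), Tlr4 (-0.30 ± 0.10, adjusted p = 0.0593) and Tnf (0.15 ± 0.17, adjusted p = 0.611) did not pass.

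Macrophage and Kupffer cell markers were 0 higher and 11 lower of 16 (0 and 13 adjusted over the list alone), with a median log2 change of -0.76. Among them were the lysozyme Lyz1 (-1.50 ± 0.23), Cd5l (-2.12 ± 0.36) and Tyrobp (-1.32 ± 0.19). Macrophage markers gave camera adjusted p = 9.1e-08, and adjusted p = 0.295 with an estimated correlation. The complement genes C1qa (-1.23 ± 0.19) and C1qc (-1.28 ± 0.13), which macrophages make, also fell. Complement as a whole was 0 higher and 2 lower of 19 (0 and 2 adjusted over the list alone) with camera adjusted p = 0.832. Lipogenesis and cholesterol synthesis genes were 1 higher and 6 lower of 24 (2 and 10 adjusted over the list alone). Lipogenesis genes gave camera adjusted p = 0.0253, and adjusted p = 0.766 with an estimated correlation. Lipogenesis genes ranged from 0.00197 to 0.329 by camera with 1 array left out, and lost the call without gp130F/F control 1 (0.329). Fatty acid oxidation and ketogenesis genes were 0 higher and 3 lower of 24 (0 and 5 adjusted over the list alone), with the regulator Ppara at -2.11 ± 0.33. This fatty acid list gave camera adjusted p = 0.0176, and adjusted p = 0.766 with an estimated correlation. The fatty acid list ranged from 0.00144 to 0.254 by camera with 1 array left out, and lost the call without gp130F/F control 1 (0.254) and gp130F/F LPS 1 (0.0569). Oxidative and metal stress genes were 1 higher and 8 lower of 22 (1 and 8 adjusted over the list alone), with the antioxidant regulator Nfe2l2 at -1.88 ± 0.30. Oxidative stress genes gave camera adjusted p = 0.0295, and adjusted p = 0.379 with an estimated correlation. Oxidative stress genes ranged from 0.0154 to 0.0569 by camera with 1 array left out, and lost the call without gp130F/F LPS 1 (0.0569). Nr1h4 (-2.04 ± 0.23), Pck1 (-1.71 ± 0.28) and G6pc (-1.47 ± 0.34) fell, as did Herpud1 of the unfolded protein response (-1.72 ± 0.25). The stress gene Atf3 (2.08 ± 0.43) and the stellate cell marker Timp1 (1.90 ± 0.24) rose.

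Acute phase proteins were 2 higher and 2 lower of 20 (2 and 2 adjusted over the list alone) in gp130F/F livers with camera adjusted p = 0.891. Their median was 0.03, their mean -0.07 and their test upward. When arrays were scaled to equal spread the test turned downward (median -0.36), as it did for complement (-0.33). In the liver channel alone the acute phase list passed upward (median 0.18), and 16 of its 20 members had spots near the ceiling on some array. The median and mean of complement, 0.03 and -0.03, also differed in sign. Saa1 (-0.01 ± 0.20, adjusted p = 0.975) did not pass. The ratios of Saa2 (-1.93 ± 0.17) and Saa3 (-1.94 ± 0.14) were lower, while the liver channel alone gave 0.53 and 1.43 and spot medians -1.02 and -0.50, on uneven spots near the ceiling.

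The gp130F/F count of 2867 moved by over 1.5 times without gp130F/F control 1 (1725), control 2 (1640), control 3 (4998), LPS 1 (1516) or LPS 2 (1369). It was 1854 in a fit of these 6 arrays alone. Without the 3 arrays with high Xist it was 1553, a fit in which the lone gp130F/F control is assumed to vary like the other groups. In the liver channel alone oxidative stress genes lost the camera call, while xenobiotic metabolism and glucose and amino acid genes gained one, downward. Of 38 called genes named, 33 passed in all 12 fits that left out 1 array, and Got1l1, Sult3a1, Cd14, Stat3 and G6pc did not. With Xist class as a covariate Got1l1, Slc38a9, Sult3a1 (-1.25), G6pc and Cd14 lost the call. Without the 3 arrays with high Xist Sult3a1 was -1.57, and Pck1 and G6pc lost the call. Among wild type arrays, calls ended without LPS 1 (1 gene, adjusted p up to 0.0537), LPS 2 (1, 0.0566) and LPS 3 (1, 0.0545). Among gp130F/F arrays, they ended without control 1 (2 genes, adjusted p up to 0.11), control 2 (2, 0.0923), LPS 1 (3, 0.108), LPS 2 (5, 0.103) and LPS 3 (3, 0.0766).

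**Figure D1:**
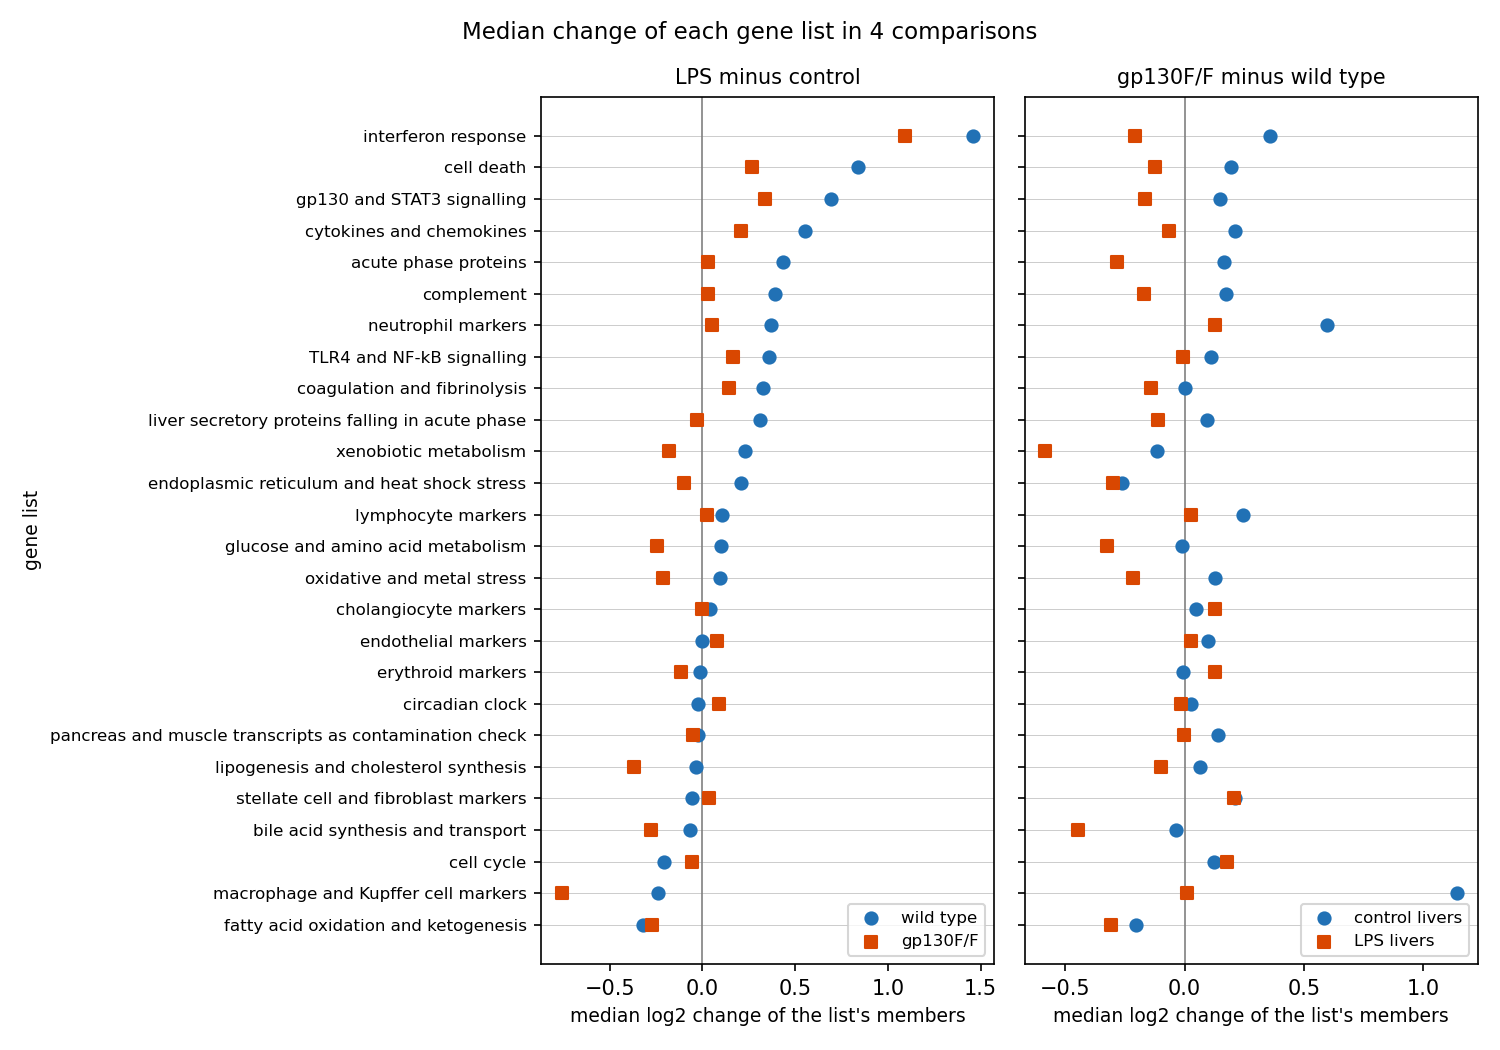
Median log2 change of the measured members of each of 26 gene lists, for LPS minus control in each genotype (left) and gp130F/F minus wild type at each treatment (right). Interferon genes lie farthest to the right with LPS in both genotypes (medians 1.46 and 1.09), and macrophage markers lie at 1.14 in gp130F/F against wild type controls and at 0.01 after LPS.

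The third comparison asks how the genotypes differed without LPS. The largest differences upward in gp130F/F controls were in Fhod3 (3.24 ± 0.55), Cxcl1 (3.11 ± 0.20), Marco (2.97 ± 0.54) and the matrix protein Spp1 (2.66 ± 0.37). Also higher were the neutrophil protease Prtn3 (2.33 ± 0.24), the lipoxygenase Alox12 (2.13 ± 0.24), Tgtp1 (2.13 ± 0.26) and the interleukin-18 inhibitor Il18bp (2.10 ± 0.22). The largest differences downward were in Slc38a9 (-2.53 ± 0.55), Rbm46os (-2.27 ± 0.55), the probe named TAK1 (-2.23 ± 0.50) and Kcnk5 (-2.19 ± 0.55). Dnase1l3 (-2.17 ± 0.48), Serp2 (-2.02 ± 0.50), Sucnr1 (-1.98 ± 0.28) and Pus3 (-1.97 ± 0.45) followed. The adjusted p of these genes ranged from 2.29e-04 (Cxcl1) to 0.0489 (Kcnk5). In all, 996 probes passed, 745 higher and 251 lower in gp130F/F, of which 258 and 81 differed by at least 2-fold. Spp1, Rbm46os and Pus3 each have 2 probes, of which 1 was called and the other went the same way.

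Macrophage and Kupffer cell markers were 10 higher and 0 lower of 16 (13 and 0 adjusted over the list alone), with a median log2 difference of 1.14. Among them were the Fc receptor chain Fcer1g (1.73 ± 0.26), the lysozymes Lyz1 (1.70 ± 0.23) and Lyz2 (1.51 ± 0.18). Macrophage markers gave camera adjusted p = 5.3e-11, and adjusted p = 0.263 with an estimated correlation. Neutrophil markers were 5 higher and 0 lower of 19 (11 and 0 adjusted over the list alone), with the integrin Itgb2 at 1.62 ± 0.29. Neutrophil markers gave camera adjusted p = 1.79e-06, and adjusted p = 0.263 with an estimated correlation. Interferon-induced genes were 10 higher and 0 lower of 37 (14 and 0 adjusted over the list alone), including Irf7 (1.27 ± 0.23) and Gbp2 (1.22 ± 0.20). Interferon genes gave camera adjusted p = 2.43e-08, and adjusted p = 0.263 with an estimated correlation. Cytokines and chemokines were 7 higher and 0 lower of 37 (10 and 0 adjusted over the list alone), including Cxcl9 (1.22 ± 0.21). Cytokines and chemokines gave camera adjusted p = 4.08e-04, and adjusted p = 0.301 with an estimated correlation. Complement genes were 4 higher and 0 lower of 19 (4 and 0 adjusted over the list alone), including C1qa (1.20 ± 0.19), C1qb (0.83 ± 0.16) and C1qc (1.31 ± 0.13). Complement genes gave camera adjusted p = 0.0145, and adjusted p = 0.263 with an estimated correlation. Complement genes ranged from 0.00261 to 0.0796 by camera with 1 array left out, and lost the call without wild type control 3 (0.0752) and gp130F/F control 1 (0.0796). Lymphocyte markers were 1 higher and 0 lower of 24 (5 and 0 adjusted over the list alone). Lymphocyte markers gave camera adjusted p = 0.00405, and adjusted p = 0.338 with an estimated correlation. Lymphocyte markers ranged from 4.38e-04 to 0.0947 by camera with 1 array left out, and lost the call without gp130F/F control 1 (0.0947). Cell death genes were 2 higher and 0 lower of 31 (5 and 0 adjusted over the list alone). Cell death genes gave camera adjusted p = 0.00399, and adjusted p = 0.338 with an estimated correlation. The arrays of this group stood apart: gp130F/F control 2 had log2 ratios of 3.39 for Marco and 2.95 for Cd14. Control 1 had 1.06 and 1.44, and control 3 had 1.65 and 1.98.

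Of the genes of LPS recognition, Lbp was higher by 1.73 ± 0.16 and Cd14 by 1.78 ± 0.34 in gp130F/F, while Tlr4 (0.08 ± 0.10, adjusted p = 0.723), Ly96 (-0.03 ± 0.14, adjusted p = 0.937) and Tnf (-0.35 ± 0.17, adjusted p = 0.236) did not pass. TLR4 and NF-kB signalling as a list was 2 higher and 0 lower of 29 (2 and 0 adjusted over the list alone) with camera adjusted p = 0.119. The list of gp130 and STAT3 signalling had 2 higher and 0 lower of 32 (4 and 0 adjusted over the list alone) with camera adjusted p = 0.228. Socs1 was higher (0.54 ± 0.11), and Socs3 (1.18 ± 0.30, adjusted p = 0.0519), Stat3 (0.29 ± 0.12, adjusted p = 0.186) and Il6st (0.41 ± 0.16, adjusted p = 0.15) did not pass. Acute phase proteins were 6 higher and 3 lower of 20 (7 and 3 adjusted over the list alone) with camera adjusted p = 0.0809, and Serpina3c (1.49 ± 0.23) and Saa2 (1.06 ± 0.17) were higher. In the liver channel alone this list passed upward (median 0.83), and 16 of the 20 had spots near the ceiling on some array. The ratio of Saa1 was lower (-1.63 ± 0.20), against 1.18 in the liver channel alone and -0.12 with spot medians, on bright and uneven spots. Icam1 was higher (1.69 ± 0.37) and the clock gene Per2 lower (-1.23 ± 0.25). Fatty acid oxidation genes were 0 higher and 4 lower of 24 (0 and 5 adjusted over the list alone), with Acot1 (-0.87 ± 0.14) and Decr1 (-0.86 ± 0.19) lower. This fatty acid list gave camera adjusted p = 9.15e-04, and adjusted p = 0.414 with an estimated correlation. The fatty acid list ranged from 1.89e-07 to 0.0588 by camera with 1 array left out, and lost the call without gp130F/F control 3 (0.0588). Lipogenesis and cholesterol synthesis genes were 4 higher and 0 lower of 24 (5 and 2 adjusted over the list alone) with camera adjusted p = 0.373, and the sterol enzymes Cyp51 (1.31 ± 0.17) and Nsdhl (1.30 ± 0.21) were higher.

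The count of 996 became 194 without wild type control 1, 132 without control 2 and 2314 without control 3, where the balance turned to 1123 higher and 1191 lower. It was 199 without gp130F/F control 2 and 2319 without control 3. Through the shared spread it became 612, 542 and 577 without wild type LPS 1, 2 and 3, and 488 without gp130F/F LPS 2. From the 6 control arrays alone limma called 0 probes, against 996 when all arrays share the spread (5017 with an unadjusted p under 0.05). Without the 3 arrays with high Xist, which leaves 1 gp130F/F control, it called 2615, of which 485 are among the 996 in the same direction. Scaling the arrays to equal spread gave 1977 probes, 62.3% of them higher against 74.8%. In the liver channel alone the lists of xenobiotic, bile acid, glucose and amino acid metabolism, of endoplasmic reticulum stress and of the clock gained a camera call downward, and coagulation and stellate cell markers one upward. Of 38 called genes named, 15 passed in all 12 fits that left out 1 array. These were Cxcl1, Spp1, Prtn3, Alox12, Tgtp1, Il18bp, Sucnr1, Lbp, Saa1, Fcer1g, Lyz1, Lyz2, C1qc, Cyp51 and Acot1. With Xist class as a covariate the call was lost by Slc38a9, Rbm46os, TAK1, Kcnk5, Dnase1l3, Serp2, Pus3, Per2 and Icam1, and without the 3 arrays with high Xist by C1qb and Icam1. Among wild type arrays, calls ended without control 1 (18 genes, adjusted p up to 0.173), control 2 (23, 0.191), LPS 1 (4, 0.0685), LPS 2 (9, 0.0739) and LPS 3 (5, 0.0706). Among gp130F/F arrays, they ended without control 1 (5 genes, adjusted p up to 0.0927), control 2 (17, 0.178), control 3 (1, 0.0543), LPS 1 (6, 0.0568), LPS 2 (10, 0.0757) and LPS 3 (3, 0.0562).

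**Figure D2:**
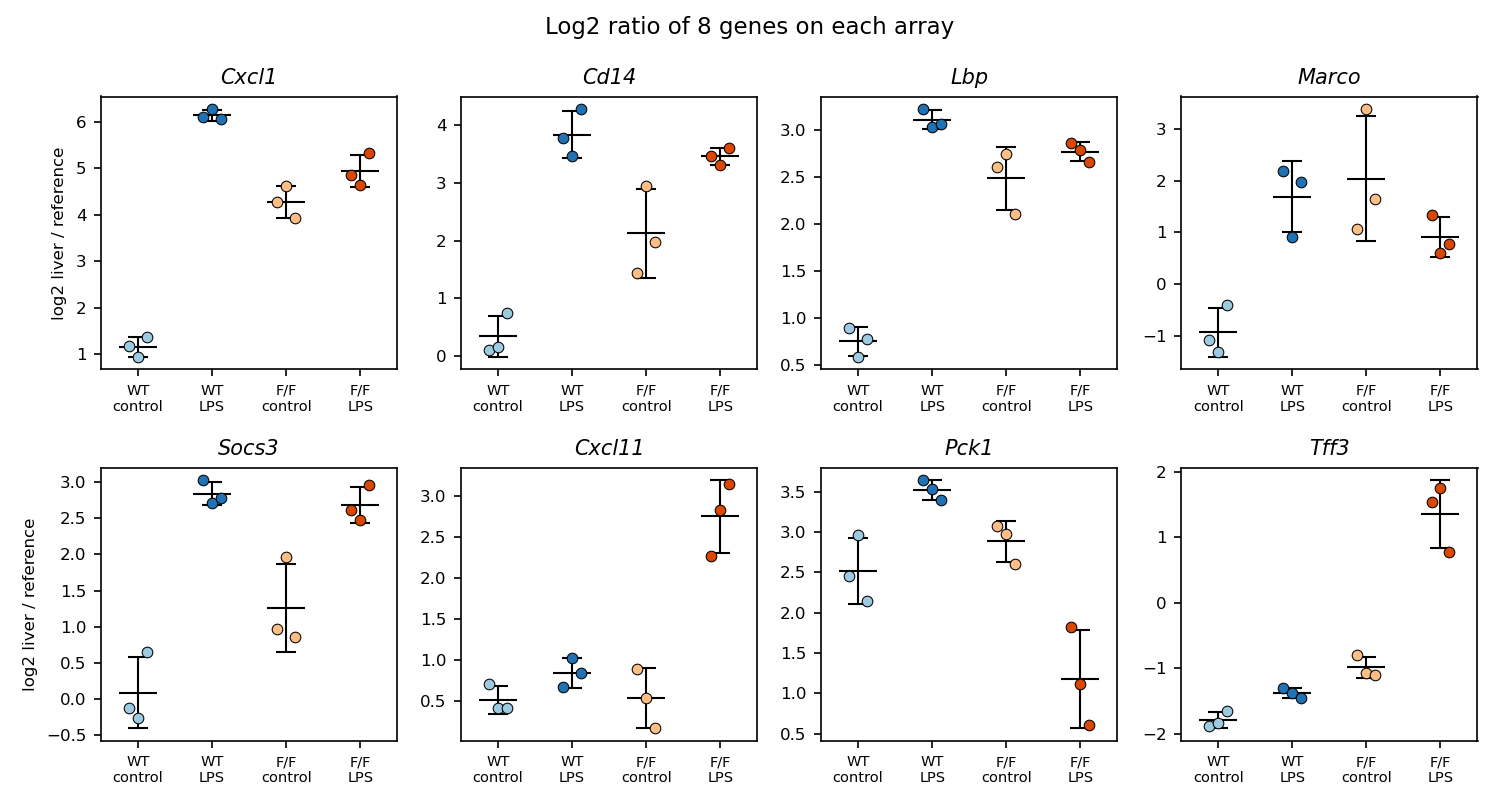
Log2 ratio of liver over embryo reference for 8 genes on each of the 12 arrays (points), with the mean and SD of each group of 3 (lines). Lbp lies between 2.10 and 2.74 on the gp130F/F control arrays, above the 3 wild type controls (0.58 to 0.89), and gp130F/F control 2 has the highest Marco (3.39) and Cd14 (2.95) of the 6 controls.

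The fourth comparison asks how the genotypes differed after LPS. Higher in gp130F/F were the secreted trefoil protein Tff3 (2.74 ± 0.21), Add2 (2.12 ± 0.55), Mdga1 (1.94 ± 0.47) and the transcription regulator Cited2 (1.92 ± 0.39). The chemokine Cxcl11 (1.90 ± 0.23), the amino acid transporter Slc43a1 (1.88 ± 0.33), Dnajc6 (1.72 ± 0.35) and Xirp2 (1.70 ± 0.40) were also higher. Lower in gp130F/F were the lipid droplet protein Plin2 (-2.62 ± 0.25), Pck1 (-2.35 ± 0.28), Herpud1 (-2.32 ± 0.25) and Alas1 (-2.29 ± 0.37). Serpina12 (-2.29 ± 0.38), the stress gene Ddit3 (-2.20 ± 0.24), Rab30 (-2.18 ± 0.43) and Reg3b (-2.15 ± 0.36) were also lower. The adjusted p of these genes ranged from 1.77e-04 (Tff3) to 0.041 (Add2). In all, 1750 probes passed, 602 higher and 1148 lower in gp130F/F, of which 148 and 189 differed by at least 2-fold. Of the 2 Add2 probes 1 was called, and the other went the opposite way.

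Most metabolic lists were lower in gp130F/F after LPS by camera. Xenobiotic metabolism was 0 higher and 7 lower of 47 (0 and 15 adjusted over the list alone), with a median log2 difference of -0.58. Among its members were Cyp2c40 (-1.22 ± 0.33), Cyp1a2 (-1.09 ± 0.27) and Cyp2e1 (-0.93 ± 0.23). Xenobiotic metabolism gave camera adjusted p = 1.8e-05, and adjusted p = 0.371 with an estimated correlation. Glucose and amino acid metabolism was 0 higher and 6 lower of 26 (0 and 6 adjusted over the list alone), including Got1 (-1.24 ± 0.21) and the ornithine transporter Slc25a15 (-1.10 ± 0.16). Glucose and amino acid genes gave camera adjusted p = 7.84e-04, and adjusted p = 0.371 with an estimated correlation. Fatty acid oxidation was 0 higher and 2 lower of 24 (0 and 2 adjusted over the list alone), with Eci2 at -0.95 ± 0.11. This fatty acid list gave camera adjusted p = 0.00446, and adjusted p = 0.648 with an estimated correlation. Lipogenesis and cholesterol synthesis was 0 higher and 2 lower of 24 (1 and 5 adjusted over the list alone) with camera adjusted p = 0.258, and the malic enzyme Me1 was lower (-1.81 ± 0.27). Bile acid synthesis and transport was 0 higher and 2 lower of 26 (0 and 0 adjusted over the list alone). Bile acid genes gave camera adjusted p = 0.038, and adjusted p = 0.691 with an estimated correlation. Bile acid genes ranged from 0.00433 to 0.134 by camera with 1 array left out, and lost the call without wild type LPS 1 (0.0696), wild type LPS 2 (0.0626), gp130F/F LPS 1 (0.134) and gp130F/F LPS 2 (0.0684). Endoplasmic reticulum and heat shock stress was 0 higher and 5 lower of 24 (1 and 7 adjusted over the list alone). Endoplasmic reticulum stress genes gave camera adjusted p = 0.00481, and adjusted p = 0.205 with an estimated correlation. Oxidative and metal stress was 0 higher and 2 lower of 22 (0 and 3 adjusted over the list alone), with Nfe2l2 at -1.67 ± 0.30. Oxidative stress genes gave camera adjusted p = 0.0211, and adjusted p = 0.371 with an estimated correlation. Oxidative stress genes ranged from 0.00489 to 0.106 by camera with 1 array left out, and lost the call without wild type LPS 2 (0.0626) and gp130F/F LPS 1 (0.106).

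Among inflammatory genes, Cxcl1 was lower in gp130F/F after LPS (-1.21 ± 0.20), with its wild type spots near the ceiling. Crp (-0.67 ± 0.17), Ly96 (-0.57 ± 0.14) and the inflammatory caspase Casp4 (-1.01 ± 0.10) were lower, and Gadd45a (1.10 ± 0.18), Timp1 (1.23 ± 0.24) and Prtn3 (1.41 ± 0.24) higher. The size for Crp is not exact, as it was near the ceiling on 1 wild type and 2 gp130F/F LPS arrays, and the liver channel alone gave -0.25. Acute phase proteins were 0 higher and 1 lower of 20 (0 and 1 adjusted over the list alone). Acute phase proteins gave camera adjusted p = 0.00446, and adjusted p = 0.361 with an estimated correlation. Interferon-induced genes were 0 higher and 4 lower of 37 (1 and 7 adjusted over the list alone). Interferon genes gave camera adjusted p = 0.0211, and adjusted p = 0.648 with an estimated correlation. Interferon genes ranged from 0.00552 to 0.0741 by camera with 1 array left out, and lost the call without wild type LPS 2 (0.0626) and wild type LPS 3 (0.0741). The ratios of Ifit1 (-1.76 ± 0.28) and Rsad2 (-0.88 ± 0.14) were lower, against 0.03 and 0.26 in the liver channel alone. Cell cycle genes were 1 higher and 0 lower of 26 (0 and 0 adjusted over the list alone). Cell cycle genes gave camera adjusted p = 0.0407, and adjusted p = 0.691 with an estimated correlation. Cell cycle genes ranged from 0.0172 to 0.106 by camera with 1 array left out, and lost the call without wild type LPS 1 (0.053), wild type LPS 2 (0.0626), wild type LPS 3 (0.055), gp130F/F LPS 1 (0.106) and gp130F/F LPS 2 (0.062). Il6st (-0.37 ± 0.16, adjusted p = 0.175), Socs3 (-0.16 ± 0.30, adjusted p = 0.78), Stat3 (-0.25 ± 0.12, adjusted p = 0.235) and Tlr4 (0.06 ± 0.10, adjusted p = 0.719) did not pass. Nor did Cd14 (-0.38 ± 0.34, adjusted p = 0.525), Lbp (-0.34 ± 0.16, adjusted p = 0.203), Saa1 (-0.25 ± 0.20, adjusted p = 0.486), Saa2 (-0.12 ± 0.17, adjusted p = 0.697) and Tnf (-0.49 ± 0.17, adjusted p = 0.0968), of which Cd14 and Saa2 had spots near the ceiling in both genotypes.

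The count of 1750 became 670 without wild type LPS 1 and 752 without LPS 2. It was 854, 634 and 961 without gp130F/F LPS 1, 2 and 3, and 3018 without gp130F/F control 3, which enters through the shared spread. Scaling the arrays to equal spread gave 804 probes, 18.5% of them higher against 34.4%. Median centring in place of loess gave 776, a fit of these 6 arrays alone 3493, the liver channel alone 91 and the fit without the 3 arrays with high Xist 3888. In the liver channel alone the lists of acute phase, interferon, bile acid, oxidative stress and cell cycle genes lost the camera call. Of 33 called genes named, 21 passed in all 12 fits that left out 1 array. These were Tff3, Cxcl11, Slc43a1, Plin2, Pck1, Herpud1, Alas1, Serpina12, Ddit3, Reg3b, Cxcl1, Ifit1, Rsad2, Got1, Slc25a15, Nfe2l2, Gadd45a, Casp4, Prtn3, Eci2 and Me1. Cyp2c40 lost the call with Xist class as a covariate. Among wild type arrays, calls ended without control 1 (1 gene, adjusted p up to 0.0559), control 2 (3, 0.0698), LPS 1 (12, 0.126), LPS 2 (9, 0.141) and LPS 3 (5, 0.0842). Among gp130F/F arrays, they ended without control 2 (3 genes, adjusted p up to 0.0635), LPS 1 (8, 0.126), LPS 2 (11, 0.155) and LPS 3 (9, 0.112).

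The fifth comparison asks whether the response to LPS differed between the genotypes, as the interaction of genotype and LPS. A negative value means a lower change with LPS in gp130F/F than in wild type. It can be a smaller rise, a larger fall, or a fall in place of a rise. A positive value means the reverse, and for Sucnr1 and G0s2, which fell in wild type, it was a smaller fall. Of the genes that rose in wild type livers and were already higher in gp130F/F controls, Cxcl1 (-4.32 ± 0.29), Marco (-3.75 ± 0.76) and Fhod3 (-3.68 ± 0.77) had the most negative values. Tgtp1 (-2.89 ± 0.36), Cd14 (-2.16 ± 0.48) and Lbp (-2.07 ± 0.22) followed the same pattern. Serinc3 (-3.19 ± 0.28), Ly6a (-2.82 ± 0.54), Tnfrsf12a (-2.81 ± 0.47) and the protease inhibitor Slpi (-2.77 ± 0.66) were also among the most negative. Positive values were found for Sema5b (2.69 ± 0.55), Sucnr1 (2.16 ± 0.40), Sgip1 (2.13 ± 0.46) and Tff3 (1.94 ± 0.30). Cxcl11 (1.88 ± 0.32), G0s2 (1.64 ± 0.31) and Fzd6 (1.49 ± 0.32) were positive too. The sizes are not exact for Cxcl1, near the ceiling on the 3 wild type LPS arrays, for Tgtp1, near it on 3 of the 6 LPS arrays, and for Cd14, near it on 5 of the 6. A ceiling in both LPS groups makes the value of a gene with higher gp130F/F controls negative by itself, and the call for Cd14 was lost in the liver channel alone. The adjusted p of these genes ranged from 2.78e-04 (Cxcl1) to 0.0452 (Slpi). In all, 749 probes passed, 73 positive and 676 negative.

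Interferon-induced genes were 0 higher and 12 lower of 37 (0 and 19 adjusted over the list alone), with a median of -0.78 and Irf7 at -1.91 ± 0.33. Interferon genes gave camera adjusted p = 2.83e-08, and adjusted p = 0.26 with an estimated correlation. Macrophage and Kupffer cell markers were 0 higher and 5 lower of 16 (1 and 8 adjusted over the list alone), including Fcer1g (-1.85 ± 0.37), Ctss (-1.35 ± 0.21) and Lyz2 (-1.53 ± 0.26). Macrophage markers gave camera adjusted p = 1.68e-04, and adjusted p = 0.33 with an estimated correlation. Neutrophil markers were 0 higher and 1 lower of 19 (0 and 2 adjusted over the list alone). Neutrophil markers gave camera adjusted p = 0.00562, and adjusted p = 0.33 with an estimated correlation. Acute phase proteins were 1 higher and 5 lower of 20 (1 and 9 adjusted over the list alone), with Serpina3c (-2.17 ± 0.33), Crp (-1.52 ± 0.24) and Saa2 (-1.18 ± 0.24) negative. Crp was near the ceiling on 3 of the 6 LPS arrays, so its size is not exact. Saa1 was 1.38 ± 0.29 in the ratio, against -1.59 in the liver channel alone. Acute phase proteins gave camera adjusted p = 0.00116, and adjusted p = 0.26 with an estimated correlation. Cytokines and chemokines were 1 higher and 7 lower of 37 (1 and 11 adjusted over the list alone), with Cxcl9 at -2.0 ± 0.29. The sizes for Cxcl9 and Saa2 rest on LPS spots that were near the ceiling on all 6 arrays, and both calls were lost in the liver channel alone, that of Saa2 also with spot medians. Cytokines and chemokines gave camera adjusted p = 0.00135, and adjusted p = 0.33 with an estimated correlation. Complement genes were 0 higher and 3 lower of 19 (0 and 4 adjusted over the list alone), including C1qb (-1.17 ± 0.23) and C1qc (-1.06 ± 0.19). Complement genes gave camera adjusted p = 0.00793, and adjusted p = 0.26 with an estimated correlation. Cell death genes were 1 higher and 3 lower of 31 (1 and 3 adjusted over the list alone), with Gadd45a at 1.07 ± 0.26. Cell death genes gave camera adjusted p = 0.00344, and adjusted p = 0.33 with an estimated correlation. Endothelial markers were 0 higher and 1 lower of 15 (0 and 1 adjusted over the list alone) with camera adjusted p = 0.961, and Icam1 was negative (-2.36 ± 0.53).

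The list of gp130 and STAT3 signalling had 0 higher and 1 lower of 32 (0 and 2 adjusted over the list alone). gp130 and STAT3 signalling gave camera adjusted p = 0.0223, and adjusted p = 0.33 with an estimated correlation. gp130 and STAT3 signalling ranged from 0.00594 to 0.0851 by camera with 1 array left out, and lost the call without gp130F/F control 1 (0.0851). Il6st (-0.78 ± 0.22, adjusted p = 0.0892), Socs3 (-1.34 ± 0.42, adjusted p = 0.126) and Stat3 (-0.54 ± 0.17, adjusted p = 0.131) did not pass. TLR4 and NF-kB signalling as a list was 0 higher and 3 lower of 29 (0 and 3 adjusted over the list alone) with camera adjusted p = 0.0641, and Tlr4 (-0.01 ± 0.14, adjusted p = 0.976), Ly96 (-0.54 ± 0.20, adjusted p = 0.197) and Tnf (-0.14 ± 0.23, adjusted p = 0.792) did not pass. Oxidative and metal stress was 0 higher and 1 lower of 22 (0 and 3 adjusted over the list alone). Oxidative stress genes gave camera adjusted p = 0.00135, and adjusted p = 0.26 with an estimated correlation. Xenobiotic metabolism was 0 higher and 1 lower of 47 (0 and 5 adjusted over the list alone). Xenobiotic metabolism gave camera adjusted p = 0.00202, and adjusted p = 0.349 with an estimated correlation. Xenobiotic metabolism ranged from 2.55e-04 to 0.066 by camera with 1 array left out, and lost the call without gp130F/F control 1 (0.066). Glucose and amino acid metabolism was 0 higher and 2 lower of 26 (0 and 6 adjusted over the list alone), with Pck1 at -2.71 ± 0.40. Glucose and amino acid genes gave camera adjusted p = 0.00615, and adjusted p = 0.33 with an estimated correlation. Glucose and amino acid genes ranged from 0.00131 to 0.137 by camera with 1 array left out, and lost the call without gp130F/F control 1 (0.137). Lipogenesis and cholesterol synthesis was 0 higher and 3 lower of 24 (0 and 4 adjusted over the list alone), including Sqle (-1.44 ± 0.28) and Cyp51 (-1.08 ± 0.24). Lipogenesis genes gave camera adjusted p = 0.0429, and adjusted p = 0.543 with an estimated correlation. Lipogenesis genes ranged from 0.00275 to 0.358 by camera with 1 array left out, and lost the call without wild type control 2 (0.0876), wild type LPS 2 (0.0607), gp130F/F control 1 (0.358), gp130F/F LPS 1 (0.0659) and gp130F/F LPS 2 (0.0666). Endoplasmic reticulum and heat shock stress was 0 higher and 3 lower of 24 (0 and 4 adjusted over the list alone) with camera adjusted p = 0.176, and Herpud1 (-1.93 ± 0.35) and Ddit3 (-1.56 ± 0.34) were negative.

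The interaction count of 749 became 410 without wild type control 1 and 267 without control 2. It was 314 and 305 without wild type LPS 1 and 2, 358 without gp130F/F control 2, and 371 and 333 without gp130F/F LPS 1 and 2. Without gp130F/F control 3 it was 2950. Median centring in place of loess gave 245 probes and the liver channel alone 20. There the lists of gp130 and STAT3 signalling, xenobiotic metabolism, lipogenesis, glucose and amino acid metabolism, cell death and complement lost the camera call. Of 35 called genes named, 15 passed in all 12 fits that left out 1 array. These were Tff3, Cxcl11, Cxcl1, Serinc3, Tgtp1, Tnfrsf12a, Serpina3c, Lbp, Crp, Cxcl9, Irf7, Pck1, Ctss, Lyz2 and C1qc. Fzd6, Slpi, Cd14, Cyp51, Ddit3 and Gadd45a lost the call with Xist class as a covariate. Without the 3 arrays with high Xist it was lost by Sema5b, Sgip1, G0s2, Fzd6, Slpi, Crp, Cyp51, Pck1, Gadd45a, C1qb, Lyz2 and Icam1. Among wild type arrays, calls ended without control 1 (12 genes, adjusted p up to 0.0948), control 2 (17, 0.117), control 3 (2, 0.0661), LPS 1 (18, 0.113), LPS 2 (17, 0.12) and LPS 3 (8, 0.0824). Among gp130F/F arrays, they ended without control 1 (11 genes, adjusted p up to 0.0782), control 2 (13, 0.0928), LPS 1 (12, 0.0905), LPS 2 (17, 0.112) and LPS 3 (9, 0.096).

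**Figure D3:**
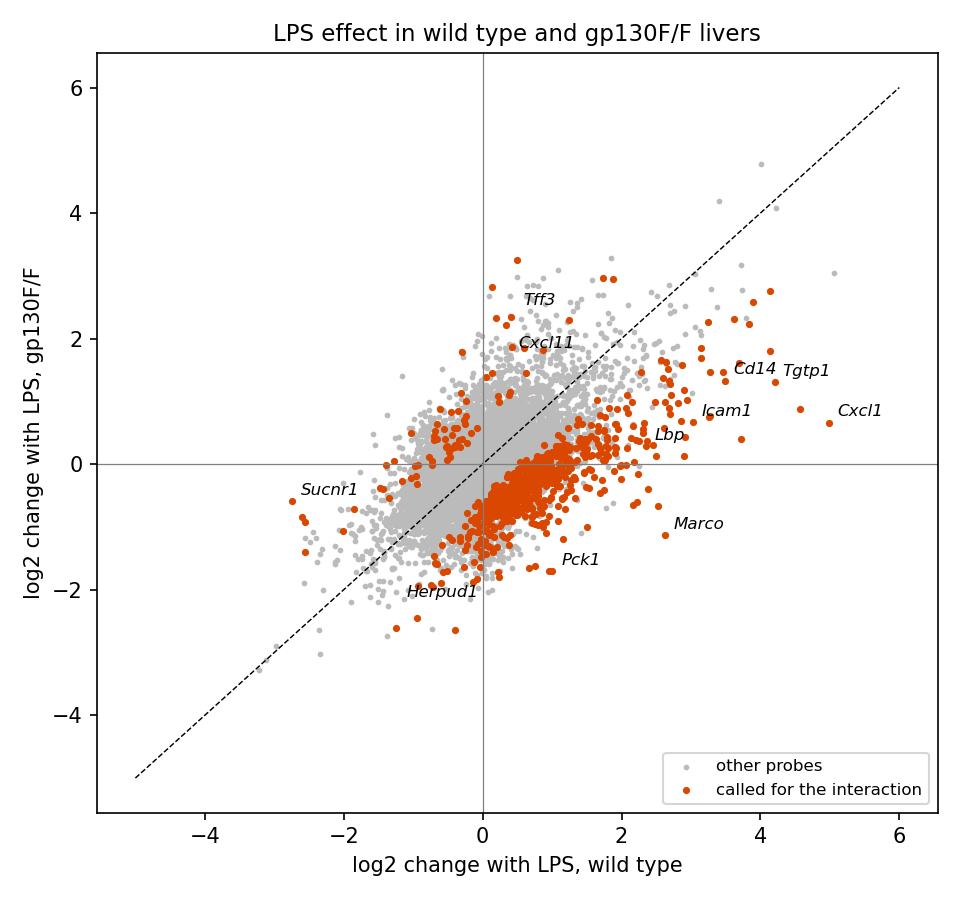
Log2 change with LPS of each of 22022 probes in wild type (horizontal) and gp130F/F livers (vertical), with the dashed line of equal change and the 749 probes called for the interaction in orange. Most of the orange points (676) lie under the line, where Cxcl1, Marco, Cd14 and Lbp are found.

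The size of the whole response was compared over the 4928 probes called for the LPS effect averaged over genotypes. It is signed so that a negative value means a smaller change in gp130F/F. The median was -0.06 on the log2 scale (exact permutation test of genotype within treatment, 2-sided, 400 arrangements, p = 0.27). For the 2284 probes raised by LPS it was -0.18 (exact permutation p = 0.045, adjusted over these 3 sets 0.135), and 64.9% of them changed less in gp130F/F. Their median change was 0.66 in wild type and 0.45 in gp130F/F. For the 2644 probes lowered by LPS the median was 0.03 (exact permutation p = 0.745). Over all 4928 probes it was 0.105 without gp130F/F control 3 and -0.107 without gp130F/F control 1 (exact permutation p = 0.04, the range with 1 array left out being 0.04 to 0.885). None of the 26 lists passed the same test after adjustment. The lowest were interferon response (median -0.78, exact permutation p = 0.005, adjusted p = 0.0867) and cell death and circadian clock (exact permutation p = 0.01, adjusted p = 0.0867 for both). For the genotypes at one treatment, 20 arrangements allow no exact permutation p under 0.1.

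Across all probes, which are not independent replicates, the LPS effects in the 2 genotypes correlated with Pearson's r = 0.50 and Spearman's rho = 0.363. Probes higher with LPS in both genotypes numbered 509, lower in both 653, and 72 were called in opposite directions. Independent lists would share 89.6 and 128, but a spread estimated from all arrays can itself raise such overlaps. The difference between control livers and the LPS effect in wild type share their wild type controls. They had 410 called probes in common, 369 in the same direction. Of these 296 were higher in both, against 65.0 for independent lists, and 73 lower in both, against 17.4. The correlation of their log2 changes was 0.20. Simulated groups without effect that share controls gave 0.503. That value is set by the shared group alone, so it does not compare with a correlation over probes that hold effects. The covariance was 0.0396, of which shared controls alone give 0.0198. With 3 controls a split into parts of at least 2 is not possible, so part of the overlap can come from the shared controls.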

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

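The tests of dye bleed, of spot medians and of an artefact at the Xist probe were chosen only after the result was seen, as were the use of the liver channel alone and of Xist class as a covariate; the other tests here were planned. The response to LPS differed between the genotypes at 749 probes by the interaction test, 676 of them with a lower change in gp130F/F. Among genes of immune cells and of recognition of LPS, the difference in log2 change was -4.32 for Cxcl1, -3.75 for Marco, -2.16 for Cd14, -2.07 for Lbp, -2.0 for Cxcl9 and -2.36 for Icam1. It was -1.85 for Fcer1g, -1.35 for Ctss, -1.53 for Lyz2, -1.17 for C1qb and -1.06 for C1qc. Of the interferon and acute phase genes, Tgtp1 differed by -2.89, Ly6a by -2.82, Irf7 by -1.91, Serpina3c by -2.17, Crp by -1.52 and Saa2 by -1.18. Saa1 differed by 1.38 in the ratio and by -1.59 in the liver channel alone. For metabolic and stress genes the values were -2.71 (Pck1), -1.44 (Sqle), -1.08 (Cyp51), -1.93 (Herpud1) and -1.56 (Ddit3). Fhod3 (-3.68), Serinc3 (-3.19), Tnfrsf12a (-2.81) and Slpi (-2.77) were also lower. The sizes are not exact for genes near the scanner ceiling with LPS: Cxcl1 (3 wild type arrays), Tgtp1 and Crp (3 of 6 LPS arrays), Cd14 (5 of 6), and Cxcl9 and Saa2 (all 6). Where both LPS groups are near it, higher gp130F/F controls give a negative value by themselves, and the calls for Cd14, Cxcl9 and Saa2 were lost in the liver channel alone. Higher changes in gp130F/F were found for Sema5b (2.69), Sucnr1 (2.16), Sgip1 (2.13), Tff3 (1.94), Cxcl11 (1.88), G0s2 (1.64), Fzd6 (1.49) and Gadd45a (1.07). For Sucnr1 and G0s2, which fell with LPS in wild type, this was a smaller fall. A lower change can likewise be a smaller rise or a larger fall.

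For the interaction, 100 of the 200 distinct arrangements of genotype within treatment were fitted. Of these, 3 including the real one called at least as many probes, under the planned share of 0.05. Reassigning genotype also removes genotype differences that are the same at both treatments, so this share does not exclude chance for the interaction itself. The others that reached the count kept the LPS livers under their own genotype. The highest of the others, 2441 probes, exchanged gp130F/F control 3 with wild type control 1, and a further arrangement that moved control arrays called 760. A count several times the real one, as the first of these, points to a structure among the control arrays beside genotype. Each pair comparison has 10 splits, too few for a share under 0.05. Limma called 3448 probes for LPS in wild type and at most 0 in another split, where up to 1279 had an unadjusted p under 0.05 against 6581. For LPS in gp130F/F it called 2867 against at most 0 (unadjusted 6357 and at most 5275). Between controls it called 996 against at most 1 (unadjusted 5017 and at most 4110), and between LPS livers 1750 against at most 0 (unadjusted 5557 and at most 1309). Only the real splits reached their counts. Others mix the groups, so a real effect would lower their counts.

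For probes raised by LPS the median difference in response between gp130F/F and wild type was -0.1805 (exact permutation p = 0.045). Adjusted over the 3 sets it did not pass (0.135), and p was 0.27 for all probes and 0.745 for those lowered by LPS. The value over all probes was -0.057, and 0.105 without gp130F/F control 3. Reassigning genotype limits these tests as above.

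Part of the difference between gp130F/F and wild type controls had the direction of the wild type LPS response, with 296 probes higher in both comparisons. Of interferon genes 10 of 37 and of cytokines and chemokines 7 of 37 were higher without LPS, and both lists lost the call with an estimated correlation (adjusted p = 0.263 and 0.301). The mix of Xist classes among the controls stays open. Within the controls with low Xist a median of 0.931 of the difference was left (quartiles 0.713 and 1.13), but this does not decide, although the planned bound was passed: the probes were chosen by a call that includes the lone gp130F/F array of that class. With Xist class as a covariate, 524 probes were called between controls against 996, and without the 3 arrays with high Xist 2615, so these counts do not decide either. The shared wild type controls stay open, because with different wild type controls in the comparisons the covariance ranged from -0.0599 to 0.0620 and was above 0 in 4 of 6 arrangements. Inflammation of the mutant liver before LPS, which the genotype could bring, also stays open and was not separated from the shared controls by these tests.

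In the reference channel, which holds the same embryo pool on every array, 33 probes changed with LPS, 23 higher and 10 lower. The largest changes were in Saa3 (3.43), Cxcl9 (3.29), Isg15 (2.89), Saa2 (2.80) and Ifit1 (2.65), and Gpr3 (-2.44), Apol9b (1.84) and Cd14 (1.78) followed. The liver channel was called in the same direction for 30 of them. The ratio fell with LPS while the liver channel rose at 4 probes in wild type and 2 in gp130F/F, together 6 cases in which a probe can count once per genotype. A constant share of liver dye read in the reference channel is argued against as the whole cause: over 243 cases, counted in the same way, the reference change per liver change had an interquartile range 1.75 times its median of 0.102. Liver signal near the scanner ceiling stays open as a candidate cause, since 100% of the 6 cases were near it on at least 1 LPS array. Uneven pixels stay open too, as 66.7% of the 6 cases were still lower with spot medians. No biological explanation was tested for it.

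Xist was high on 3 control arrays (log2 ratio -0.01 to 0.56) and at least 1.77 lower on the other 9, although all mice are labelled female. An artefact at the Xist probe is argued against, because Cyp3a16, a cytochrome of female livers, was also higher on these 3 arrays than on the other 9, by at least 2.19. Mice of different sex stay open. Of 2 genes higher in male livers, neither separates the 3 arrays: Cyp7b1 was 0.82 to 2.06 on them and 1.54 to 5.32 on the others, and Elovl3 -0.18 to 0.02 and -0.12 to 2.03. Over 15 further genes that differ between male and female livers, the mean difference in the predicted direction was 0.425, with 12 of 15 genes in that direction. Of the 20 splits of the 6 controls it ranked 2, the highest other being 0.513. The Y-linked Kdm5d did not decide, with -1.31 to -1.03 on the 3 arrays and -1.09 to -0.26 on the others, nor did Uty (1.88 to 3.15 and 2.25 to 4.2). As 2 of the 3 arrays are gp130F/F controls, sex, if it differed, would be mixed with both genotype and treatment.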

How the results depend on the processing

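The liver channel alone, spot medians, leaving out spots near the ceiling and the Xist alternatives were tried only after the data had been seen, and the others were planned. With no background correction, plain subtraction, a trended and robust prior, leaving out poorly detected spots or spots near the ceiling, or spot medians, each count stayed within 1.5 times its main value. With a replicate block the counts were 3176, 2531, 676, 1710 and 583 in the order wild type LPS, gp130F/F LPS, control livers, LPS livers and interaction. By the labels the arrays hold separate mice, so the numbers were not taken as pairs. Deviations of same-numbered arrays correlated with r from -0.292 to 0.5. The highest was between wild type control 1 and gp130F/F control 1, so structure shared by same-numbered arrays is not excluded. Aquantile leaves ratios unchanged and the filter on dim probes removed almost none, so both say nothing. Print-tip loess and a batch term were not run, because the files give neither blocks of spots nor scan dates. The authors' lowess table and its log2 are the same values and count as 1 alternative.

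Median centring gave 631 probes in control livers, 776 in LPS livers and 245 for the interaction. Scaling between arrays gave 1977 in control livers, 969 of them among the 996, and 804 in LPS livers. The authors' values gave 478 for the interaction and hold no genotype effect at one treatment. Fits of the compared groups alone gave 1854 in gp130F/F, 3493 in LPS livers and 0 in control livers, against 996 from all arrays (5017 at an unadjusted p under 0.05); fewer arrays set the spread there. Array weights gave 5946, 11105, 10187, 4509 and 7096 in the order above, with weights from 0.227 (gp130F/F control 3) to 9.18 (gp130F/F control 2). Their estimate stopped before it converged, so these counts are no guide. The liver channel alone gave 936, 603, 212, 91 and 20. Without the 3 arrays with high Xist, where the lone gp130F/F control is assumed to vary like the other groups, the counts were 1553 in gp130F/F, 2615 in control livers and 3888 in LPS livers. With Xist class as a covariate they were 1077 in gp130F/F and 524 in control livers. The cause of these shifts in the counts was not tested.

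With each array left out, counts ranged from 2154 to 4314 for LPS in wild type, 1369 to 4998 in gp130F/F, 132 to 2319 in control livers, 634 to 3018 in LPS livers and 267 to 2950 for the interaction. Each highest count came without gp130F/F control 3. The response size ranged from -0.116 (without wild type LPS 3) to 0.105 (without gp130F/F control 3), with exact permutation p from 0.04 to 0.885. It passed without gp130F/F control 1 (-0.107, exact permutation p = 0.04).

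Of 6422 comparisons of 219 gene results with an alternative, 5767 kept direction and side of the threshold, 613 lost the call, 32 gained one and 10 reversed. The liver channel alone ended 79 calls, fits of the compared groups 42 and median centring 33. Of 3848 comparisons of 130 list results, 3583 were the same, 158 lost the call, 100 gained one and 7 reversed. An estimated correlation ended 48 list calls, while fry lost 12 and gained 13.

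Reversals in the liver channel alone were Saa1 (1.49), Saa2 (2.41) and Pck1 (-0.0200) with LPS in wild type, and Saa2 (0.53) and Saa3 (1.43) in gp130F/F. The others were Saa1 between controls (1.18), Ifit1 (0.0328) and Rsad2 (0.26) between LPS livers, and Saa1 in the interaction (-1.59). With spot medians Saa2 in wild type became 0.41. With scaling, wild type medians became 0.0459 for secretory proteins, -0.26 for xenobiotic metabolism and -0.40 for glucose and amino acids. In gp130F/F they became -0.36 for acute phase, -0.40 for secretory proteins and -0.33 for complement. Without the arrays with high Xist the cell cycle list in gp130F/F became -0.46. The cause of these reversals was not tested beyond the spots near the ceiling. Empty and buffer spots had a median liver intensity of 83.5 to 161 over a background of 47 to 64, so a spot above its background does not by itself show signal, and what depth limits among dim probes stays untested.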

Other observations

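The planned test here is that of the region around Il6st; the remaining values were looked up after the results had been seen. The control arrays were uneven in inflammatory genes. gp130F/F control 2 had a log2 ratio of 3.39 for Marco, 2.95 for Cd14 and 1.96 for Socs3. Wild type control 3 had a liver intensity of 45920 at the Saa1 spot, against 8995 and 7037 on the other wild type controls.

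Chromosome of the strain in which the knock-in allele was made might remain around Il6st and bring genotype differences of its own. Among 48 probes of the 100 annotated neighbours on each side of Il6st, 9 (18.8%) were called for the genotype effect averaged over treatments, against 11.3% of 13800 other named probes. The difference was not called (odds ratio 1.82, 95% interval 0.772 to 3.82, Fisher's exact test, one-sided, p = 0.086), so the hypothesis stays open.

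Names in the authors' tables and in the scanner files differ by 1 spot over spots 6771 to 6799, 7378 to 7529 and 9682 to 9739. Cxcl1 lies in one of these stretches. Across arrays its values here correlated with r = -0.563 with the authors' row of that name and with r = 0.999 with the row of the spot before, so the authors' row named Cxcl1 holds another probe's values.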
